A study of Arabidopsis thaliana with 6 samples.

How the data were processed

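The deposited table held TPM (transcript abundance scaled to a fixed total per library), computed by the authors before deposition; their processing notes name STAR 2.7.10a, RSEM 1.3.1 and the genome build TAIR10, without a role for each tool, an annotation version or a filter. Per the labels, total RNA was extracted with TransZol Up and libraries were made with a TruSeq RNA kit from 1 µg. The values were rounded to 2 decimals by the authors. TPM keeps no sequencing depth, so the depth of the libraries is unknown. The table had 31276 genes identified by AGI code and 6 library columns, all of which were used (0 were left out). The listed genes summed to less than 1000000 in every library, so the authors' scaling covered entries that the table does not list.

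Gene names came from a name table for assembly TAIR10.1, whereas the authors used TAIR10, so the table served for names only and no coordinates were used. It matched 31189 genes by AGI code; the other 87 were the 78 plastid and 9 mitochondrial genes, which were kept. The 30 gene lists with 455 genes were fixed before the data were examined, as were the tests and most alternatives. All 455 genes were in the table by AGI code, and 19 had another name in the name table.

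Genes with TPM of at least 1 in at least 3 libraries were tested, which left 18608. Day 7 was compared with day 0 by limma-trend (limma 3.58.1 in R 4.3.3) on log2(TPM + 1), with Benjamini-Hochberg adjustment over all tested genes; a gene rose or fell if its adjusted p was below 0.05. The deposited scale was used without further normalization. Folds given for single genes are ratios of group mean TPM, whereas log2 differences are on log2(TPM + 1). A fold can therefore exceed its log2 difference where a group lies near 0 TPM. Lists with at least 4 tested members were tested by limma's camera with a preset inter-gene correlation of 0.01, adjusted over 28 lists, and again with the correlation estimated from the data. The estimated form rests on the 4 residual degrees of freedom of the libraries, so it has little power. The estimated correlations ran from 0.47 (auxin-LBD callus regulators) to 0.96 (reference genes) on the deposited scale, far above the preset 0.01. After median-of-ratios scaling they ran from -0.095 (wound-induced factors) to 0.86 (photosynthesis). Where members of a list vary together more than the preset allows, the preset p-values are too small. Member counts were also made with p adjusted over the list alone. Shares of TPM were compared by exact two-sided permutation, for which 3 against 3 libraries give 0.1 as the smallest p. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

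The genes named in the text were taken by a fixed rule. From each list came the 2 members with the largest differences that passed and had a mean TPM of at least 5 in the higher group, plus the largest in the opposite direction; where fewer than 2 passed, the 2 most abundant tested members were given. Over all genes the 5 largest rises and 5 largest falls without overlap and with a mean TPM of at least 10 in the higher group were added. LBD16, LBD29, WOX11, WOX5, PLT1, PLT2, WIND1, STM and WUS were always given. A few further list members are named for their counts or calls.

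The test was tried on simulated data with the scale differences of the real libraries, with 50 genes changed at each fold among 18608. On the deposited scale it recovered 0% of 1.5-fold and 2-fold changes and 100% of 4-fold and 8-fold changes, with 12 false calls. After median-of-ratios scaling it recovered 32%, 84%, 100% and 100%, with 9 false calls. Far fewer genes were changed in the simulation than were called in the real comparison (29.6% of tested genes), which made the adjusted cutoff stricter. The recovered shares are therefore not the detection rates of the real comparison. There GAPC2, for example, passed at a log2 difference of 1.08.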

Results

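RNA-seq profiles were collected from Arabidopsis thaliana of the Col-0 accession. Hypocotyls, the embryonic stems, were cut from 1-week-old seedlings and laid on callus-inducing medium, on which cut plant tissue forms callus, a mass of dividing cells. There were 3 biological replicates from tissue collected at excision (day 0) and 3 from tissue kept on the medium for 7 days (day 7), so 6 libraries in 2 groups. The design text describes the day 0 tissue as freshly excised, whereas the tissue label of all 6 libraries reads callus. The deposited values were TPM, a measure of transcript abundance scaled to a fixed total per library, from which sequencing depth cannot be recovered, so the depth of each library is unknown and no counting intervals are given. The comparison of the groups asks how the transcriptome of the hypocotyl explant differs from that of the callus formed from it.

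The libraries differed in how much of their 1000000 TPM went to protein-coding genes. Nuclear protein-coding genes held 59.5%, 86.4% and 71.2% of the 1000000 in day 0 replicates 1, 2 and 3, and 37.6%, 81.0% and 52.0% in day 7 replicates 1, 2 and 3. The 4 genes annotated as nuclear ribosomal RNA (rRNA) held 11.4% ± 6.95 (SD, n = 3) at day 0 and 24.2% ± 15.3 (SD, n = 3) at day 7, with an exact two-sided permutation p of 0.3. AT2G01020 and AT3G41979 carried identical values in every library, and how reads common to such copies were counted is not stated. The listed genes summed to between 793808 and 922411 TPM, and 7.76% to 20.6% of the 1000000 lay on entries absent from the table. Replicate 2 had the lowest rRNA share in both groups.

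**Figure D1:**
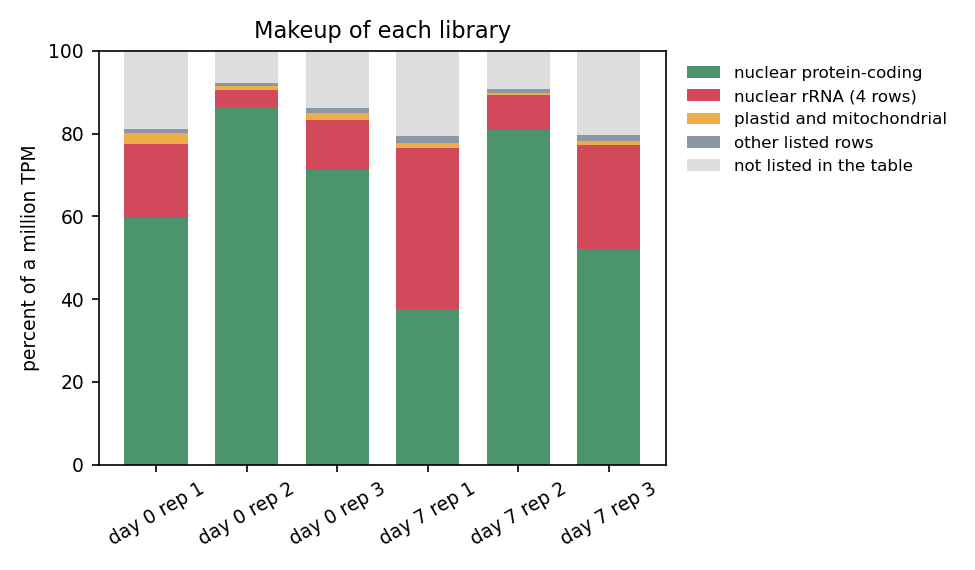
Stacked bars give the percent of 1000000 TPM held by nuclear protein-coding genes, nuclear rRNA, organelle genes, other listed genes and entries not listed, for each of the 6 libraries. The rRNA share ranged from 4.19% in day 0 replicate 2 to 38.9% in day 7 replicate 1.

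The summed plastid share was lower in the callus libraries, mostly through plastid rRNA. The 78 plastid genes held 2.18%, 0.773% and 1.55% of all TPM in the day 0 libraries and 0.313%, 0.0678% and 0.206% in the day 7 libraries, a 7.67-fold lower mean with no overlap between the groups. The plastid rRNA genes ATCG00920, ATCG00950, ATCG01180 and ATCG01210 held 56.8% to 93.8% of the plastid TPM in each library. Over all plastid genes 45 had a lower mean at day 7, 32 a higher mean and 1 equal means, and the other 74 genes summed to 1351, 1147 and 1351 TPM at day 0 and to 1351, 213 and 669 TPM at day 7. The 9 mitochondrial genes held 0.245% ± 0.114 at day 0 and 0.617% ± 0.351 at day 7 (SD, n = 3 each), and the groups overlapped. In the exact two-sided permutation test the plastid share gave p = 0.1, the smallest that 3 against 3 libraries allow, and the mitochondrial share gave p = 0.3. Both together were 1.75% ± 0.818 at day 0 and 0.813% ± 0.474 at day 7 (SD, n = 3 each), also with an exact permutation p of 0.3. The mitochondrial rRNA genes ATMG00020 and ATMG01390 held 95.9% to 98.1% of the mitochondrial TPM in each library.

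Libraries of the same group were alike and the groups were far apart. Pearson correlations of log2(TPM + 1) across the 18608 tested genes, which are not independent replicates, were 0.965 to 0.985 within groups and 0.713 to 0.751 between them. The first principal component carried 72.2% of the variance, and 88.2% after median-of-ratios scaling of the libraries. The second carried 21.3%, and 4.93% after that scaling. On the deposited scale it ordered replicates 1, 2 and 3 alike in both groups (42.3, -41.1 and 4.30 at day 0, and 63.2, -78.9 and 10.2 at day 7).

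Between day 0 and day 7, 5512 of the 18608 tested genes changed, of which 2497 rose and 3015 fell in callus (limma-trend on log2(TPM + 1), Benjamini-Hochberg adjusted p below 0.05). At least 2-fold changes on this scale were found for 5276 genes, 2368 up and 2908 down. The TPM of the 3 libraries of either group did not overlap for 7204 tested genes, or 38.7%, where chance gives 10%. The scale differences between libraries widened the errors: after median-of-ratios scaling 12153 genes changed, 5826 up and 6327 down, and 5382 (97.6%) of the calls on the deposited scale were kept in the same direction, 0 turned and 130 were lost. The split between rises and falls depended on the scale. Median-of-ratios scaling assumes that the median gene is unchanged, so its near-even split follows in part from the scaling itself. After it the median log2 difference of all genes was -0.0095. With TPM rescaled over nuclear protein-coding genes alone, a choice made after seeing the data, 13428 genes changed, 69.6% of them upward, and the median of all genes was 0.41 above 0 on the log2 scale, against 0.05 as deposited. Rescaling without the 50 most abundant genes gave 13350 changed genes, 68.1% of them upward, against 45.3% as deposited.

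At least 3 of the 5 genes with the largest falls belong to the lipid-transfer protein family. EARLI1 (AT4G12480) fell from 2895 ± 937 to 1.94 ± 2.13 TPM (SD, n = 3 each), a log2 difference of -10.20 ± 0.43 (SE, limma adjusted p = 3.53e-119), and AZI1 of the same lipid-transfer protein family (AT4G12470) fell from 1923 ± 772 to 0.850 ± 0.840 TPM, a log2 difference of -10.06. AT4G12490 of the same family fell from 881 ± 230 TPM (log2 difference -9.69 ± 0.44) and was listed at 0 in 2 of the 3 day 7 libraries, and ELP (AT1G12090, extensin-like) from 505 ± 343 to 0.530 ± 0.288 TPM. AT5G57785, of unknown function, was at 376 ± 181 TPM at day 0 and listed at 0 in all 3 day 7 libraries. How reads common to related copies were counted is not stated, so the levels of these relatives are uncertain. The largest rises were those of AT5G54370, a late embryogenesis abundant-related gene (0.287 ± 0.261 to 511 ± 201 TPM, log2 difference 8.58 ± 0.44), the methionine salvage gene ARD3 (AT2G26400, 0.977 ± 0.246 to 691 ± 379 TPM), AT1G50060 of the CAP family of secreted proteins (2.46 ± 1.36 to 858 ± 295 TPM) and the lectin gene AT1G52070 (0.200 ± 0.272 to 157 ± 104 TPM). AT1G51000, uncharacterised, was listed at 0 in all day 0 libraries and stood at 287 ± 39.0 TPM at day 7. Variances were drawn fully to a trend common to all genes in this fit, so such small p-values rank genes and do not measure each gene's own spread. The same holds for every SE given on the deposited scale.

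Regulators of auxin-driven callus and lateral root initiation were mostly higher in the excised hypocotyl than in 7-day callus. LBD29 (AT3G58190), a transcription factor downstream of the auxin response factors ARF7 and ARF19, was at 62.1 ± 15.4 TPM at day 0 and 0.380 ± 0.473 at day 7 (SD, n = 3 each), with a log2 difference of -5.54 ± 0.44 (SE, limma adjusted p = 6.84e-34). LBD16 (AT2G42430) fell 11.7-fold from 117 ± 21.8 TPM, and GATA23 (AT5G26930), a marker of lateral root founder cells, from 79.7 ± 6.76 to 0.393 ± 0.510 TPM. WOX11 (AT3G03660), which acts in root founder cells of cut organs, went the other way, from 40.5 ± 6.93 to 133 ± 48.4 TPM (3.29-fold, limma adjusted p = 8.99e-04). Of the 14 list members 8 fell, 1 rose and 5 did not pass, with the same counts adjusted over the list alone. The list was shifted down by camera with adjusted p = 4.22e-06, and adjusted p = 0.586 with an estimated correlation.

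Most tested root meristem genes rose in callus. The AP2 factors PLT1 (AT3G20840) and PLT2 (AT1G51190), which maintain the root stem cell niche, increased from 2.48 ± 0.492 to 75.6 ± 32.3 TPM (30.5-fold) and from 2.56 ± 0.907 to 22.5 ± 12.6 TPM (8.76-fold; SD, n = 3 each). RGF3 (AT2G04025) and RGF2 (AT1G13620), peptide signals of the root tip, rose from 1.78 ± 0.717 to 153 ± 39.7 TPM and from 0.773 ± 0.361 to 91.7 ± 29.7 TPM, with log2 differences of 5.79 ± 0.44 and 5.68 ± 0.45 (SE, limma adjusted p = 7.10e-37 and 7.02e-35). WOX5 (AT3G11260), the marker of the quiescent centre, stood at 17.6 ± 2.08 TPM at day 0 and 16.1 ± 8.53 at day 7 and did not pass (log2 difference -0.23 ± 0.44, limma adjusted p = 0.752), while its relative WOX7 (AT5G05770) fell 14.4-fold. Of 19 tested members 13 rose, 1 fell and 5 did not pass, the same when adjusted over the list alone. Camera gave adjusted p = 1.56e-10 for the list, and adjusted p = 0.586 with an estimated correlation.

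**Figure D2:**
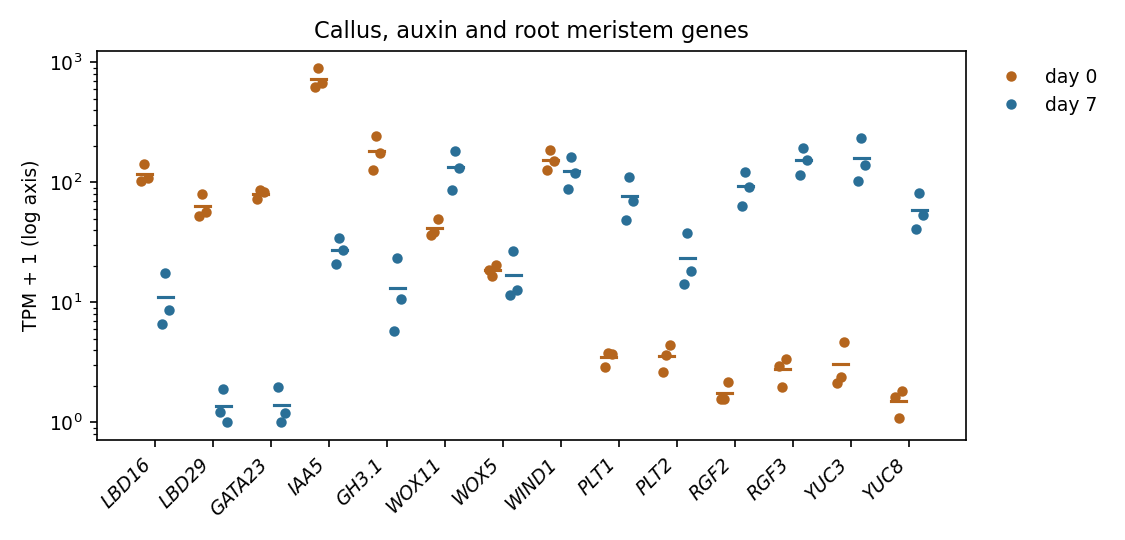
Points give TPM + 1 on a log axis in each of the 3 day 0 and 3 day 7 libraries, and horizontal lines give group means, for 14 callus, auxin and root meristem genes. LBD29 and GATA23 lay near 0 TPM at day 7, PLT1, RGF2, RGF3, YUC3 and YUC8 were higher at day 7 in all libraries, and WOX5 and WIND1 overlapped.

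Few wound regulators passed the test on the deposited scale, and shoot meristem genes went both ways. WIND1 (AT1G78080), a wound-induced driver of callus formation, was at 154 ± 30.2 TPM at day 0 and 123 ± 37.0 at day 7 (SD, n = 3 each; log2 difference -0.35 ± 0.43, limma adjusted p = 0.584), and passed as lower after median-of-ratios scaling (log2 difference -0.42 ± 0.11, limma adjusted p = 8.32e-03), but turned to 0.0885 with quantile normalization and 0.0459 with nuclear protein-coding genes only, without passing. Of 9 tested wound-induced factors 2 rose, ERF115 (AT5G07310, 2.38-fold) and ANAC071 (AT4G17980, 6.81-fold), and 7 did not pass, while 4 rose and 3 fell after scaling; ERF115 lost its call when any of 4 libraries was left out singly (each of day 0, or replicate 3 of day 7). Among 5 tested shoot meristem genes CUC2 (AT5G53950), an organ boundary factor, rose from 0.257 ± 0.222 to 15.9 ± 10.4 TPM, and 3 fell, with KNAT1 (AT4G08150) from 45.3 ± 18.4 to 10.4 ± 5.42 TPM. STM was at 0.443 ± 0.227 and 0.763 ± 0.411 TPM and WUS was listed at 0 in all libraries, so neither entered the test. Camera adjusted p was 0.426 for the wound list and 0.874 for the shoot list. AGL15 (AT5G13790) was the only embryo identity gene tested and rose 3.28-fold, and 0 of 8 stomatal lineage genes were expressed highly enough to be tested.

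Most tested primary auxin response genes fell, and 9 of 17 auxin synthesis and transport genes rose. IAA5 (AT1G15580), an early auxin-induced repressor, fell from 730 ± 141 to 26.6 ± 6.78 TPM (27.5-fold) and GH3.1 (AT2G14960), of the auxin-conjugating family, from 181 ± 58.2 to 12.3 ± 9.08 TPM (14.7-fold; SD, n = 3 each). Of 20 response genes 13 fell, 2 rose and 5 did not pass, and IAA20 (AT2G46990) was the larger of the rises, from 8.10 ± 2.23 to 33.3 ± 17.0 TPM. The flavin monooxygenases of auxin synthesis YUC3 (AT1G04610) and YUC8 (AT4G28720) rose from 2.07 ± 1.39 to 158 ± 66.5 TPM and from 0.510 ± 0.377 to 57.8 ± 20.8 TPM, with log2 differences of 5.71 ± 0.44 and 5.26 ± 0.44 (SE, limma adjusted p = 7.88e-36 and 1.56e-30). Of the 17 synthesis and transport genes 0 fell and 8 did not pass; after median-of-ratios scaling 11 rose and 3 fell. Adjusted over each list alone, the counts on the deposited scale were the same. Camera adjusted p was 6.75e-07 for the response genes, moving down, and 2.22e-07 for the synthesis and transport genes, moving up, and both had adjusted p = 0.631 with an estimated correlation.

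Cytokinin response genes did not move together. The response regulator ARR3 (AT1G59940) rose from 5.10 ± 1.95 to 65.5 ± 33.0 TPM and the cytokinin oxidase CKX3 (AT5G56970) from 16.3 ± 4.16 to 167 ± 53.6 TPM, whereas ARR7 (AT1G19050) fell from 51.7 ± 2.64 to 20.5 ± 10.1 TPM (SD, n = 3 each), a call lost without day 0 replicate 3 or day 7 replicate 3. Of 12 tested members 3 rose, 1 fell and 8 did not pass, with limma camera adjusted p = 0.426. After median-of-ratios scaling 2 rose and 5 fell, and the list did not pass (limma camera adjusted p = 0.804).

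Few cell division genes passed the test on the deposited scale, and most mitosis genes rose once the libraries were scaled. The cytokinesis syntaxin gene KNOLLE (AT1G08560) was 1.77-fold higher at day 7 without passing (limma adjusted p = 0.191), and the replication clamp PCNA2 (AT2G29570) stood at 56.4 ± 6.70 TPM at day 0 and 55.8 ± 28.7 at day 7 (SD, n = 3 each). Of 20 mitosis genes 1 rose, CYCB2;1 (AT2G17620, 2.87-fold), and 19 did not pass; its call was lost when any single day 0 library or day 7 replicate 3 was left out. CDC20.1 (AT4G33270), 2.13-fold higher at day 7, had a limma adjusted p of 0.0637. After median-of-ratios scaling 16 of the 20 rose. Among 19 DNA replication genes 1 rose, the polymerase subunit gene ICU2 (AT5G67100; lost with no filter and when any of 3 libraries was left out), and 18 did not pass, with TSO2 (AT3G27060) at 74.7 ± 7.46 and 82.9 ± 38.5 TPM, and after scaling 9 rose and 3 fell. Of 9 tested D-type cyclins 3 rose, CYCD3;3 (AT3G50070, 3.16-fold), CYCD6;1 (AT4G03270, 3.81-fold) and CYCD4;1, and 6 did not pass; scaling gave 7 rises and 2 falls. Adjusted over the lists alone, 0 mitosis, 0 replication and 3 D-type cyclin genes passed. For the 3 lists limma camera gave adjusted p = 0.0748, 0.426 and 0.220. After median-of-ratios scaling the mitosis list was shifted up (limma camera adjusted p = 1.23e-03, and adjusted p = 0.394 with an estimated correlation).

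Inhibitors of cyclin-dependent kinases split. SMR1 (AT3G10525) and SIM (AT5G04470), which promote endoreduplication, fell from 73.4 ± 21.5 to 2.47 ± 2.03 TPM (29.7-fold) and from 65.2 ± 17.9 to 6.16 ± 1.03 TPM (10.6-fold; SD, n = 3 each), and KRP7 (AT1G49620) rose 5.37-fold. Of 11 tested members 3 fell, 1 rose and 7 did not pass (4 fell and 2 rose adjusted over the list alone), with limma camera adjusted p = 0.239, and scaling gave 5 falls and 3 rises. Ribosome biogenesis genes leaned down: NUC2 (AT3G18610, a nucleolin) fell 3.28-fold and FIB2 (AT4G25630, a fibrillarin) 2.55-fold, a call lost without day 0 replicate 3 or day 7 replicate 3, and 4 of 13 fell while 9 did not pass, with limma camera adjusted p = 0.208. After median-of-ratios scaling 10 of the 13 fell and the list was shifted down (limma camera adjusted p = 1.89e-03, and adjusted p = 0.394 with an estimated correlation).

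Photosynthesis genes of the nuclear genome fell almost throughout. Of 35 tested members 34 fell and 1, PSBO2, did not pass, also when adjusted over the list alone. LHCB2.1 (AT2G05100, light-harvesting protein) went from 34.7 ± 31.5 to 0.290 ± 0.411 TPM (SD, n = 3 each). PSAL (AT4G12800, photosystem I) went from 39.8 ± 21.0 to 0.973 ± 0.455 TPM, 40.9-fold lower. Their log2 differences were -4.43 ± 0.42 and -4.27 ± 0.44 (SE from the common trend, limma adjusted p = 3.21e-24 and 1.63e-20). After median-of-ratios scaling LHCB2.1 had -4.55 ± 0.64 (SE, limma adjusted p = 4.24e-04). Day 0 levels were uneven: the TPM of the list summed to 572 and 818 in day 0 replicates 1 and 2 and to 2715 in replicate 3, against 95.3, 168 and 143 in the day 7 libraries. Single values of the near-identical LHCB1 and RBCS copies are uncertain, since how their common reads were counted is not stated; LHCB1.2 lost its call after median-of-ratios scaling. Among 14 tested genes of chlorophyll synthesis and greening 9 fell, 0 rose and 5 did not pass. CRD1 (AT3G56940) went from 26.7 ± 19.0 to 3.73 ± 1.43 TPM (7.15-fold lower), and CHLH (AT5G13630) from 9.75 ± 4.32 to 1.40 ± 0.443 TPM (6.95-fold lower, SD, n = 3 each). Camera adjusted p was 5.63e-25 for photosynthesis and 3.49e-03 for chlorophyll synthesis, with adjusted p = 0.586 and 0.828 with an estimated correlation; the chlorophyll call was lost with a TPM minimum of 5.

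Most tested surface and wall loosening genes fell. KCS1 (AT1G01120) and CER6 (AT1G68530), which elongate fatty acids for cuticular wax, fell from 182 ± 91.4 to 4.16 ± 3.09 TPM and from 252 ± 97.2 to 12.1 ± 9.68 TPM (SD, n = 3 each), and 10 of 11 tested epidermis and cuticle genes fell, with 1 not passing. Among 14 tested wall loosening genes 12 fell, 1 rose and 1 did not pass. XTH18 (AT4G30280), a xyloglucan-remodelling enzyme, fell from 441 ± 309 to 2.97 ± 1.81 TPM (149-fold, log2 difference -6.68 ± 0.44, SE), and the expansin EXPA11 (AT1G20190) was at 253 ± 155 TPM at day 0 and listed at 0 in all day 7 libraries. XTH15 (AT4G14130) rose 6.47-fold. Both lists kept these counts when adjusted over the list alone, and camera gave adjusted p = 4.26e-08 for epidermis and cuticle and 8.03e-16 for wall loosening, both with adjusted p = 0.586 with an estimated correlation.

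**Figure D3:**
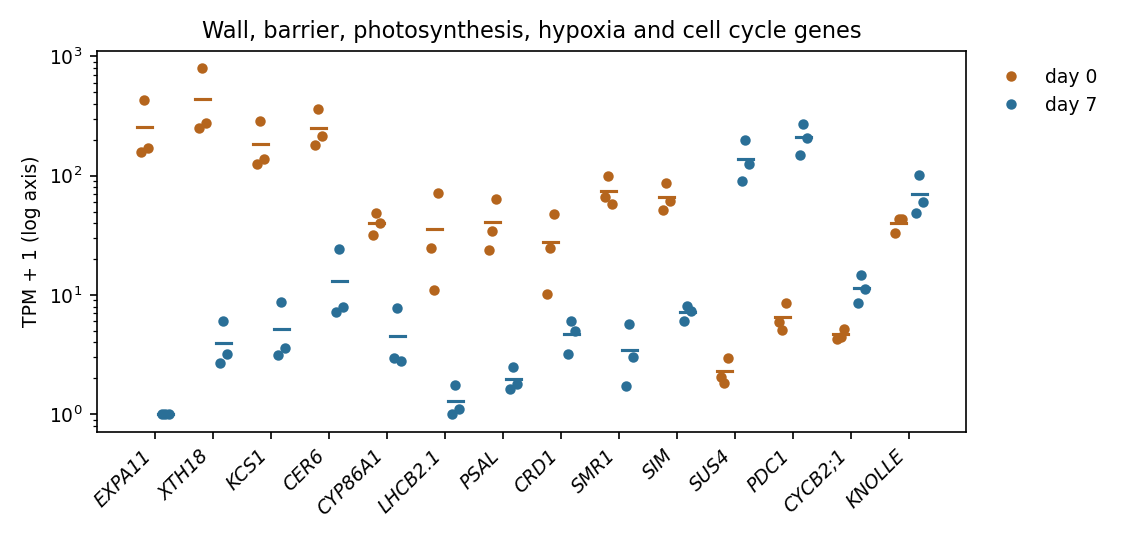
Points give TPM + 1 on a log axis in each library of day 0 and day 7, and horizontal lines give group means, for 14 wall, barrier, photosynthesis, hypoxia and cell cycle genes. EXPA11 lay at 0 TPM in all 3 day 7 libraries, SUS4 and PDC1 were higher at day 7 in all libraries, and LHCB2.1, PSAL and CRD1 were highest in day 0 replicate 3.

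Barrier, root hair and nutrient uptake genes fell in part. The suberin enzymes CYP86A1 (AT5G58860) and FAR5 (AT3G44550) fell from 39.0 ± 8.22 to 3.52 ± 2.84 TPM (11.1-fold) and from 26.2 ± 2.35 to 2.62 ± 2.28 TPM (9.97-fold; SD, n = 3 each), and 10 of 12 tested barrier genes fell, 1 did not pass and 1 rose, the endodermal regulator MYB36 (AT5G57620, 2.69-fold; lost with no filter and when any of 4 libraries was left out). Of 4 tested root hair genes 3 fell and 1 did not pass. RHD6 (AT1G66470) went from 27.2 ± 8.02 to 3.59 ± 3.24 TPM (7.58-fold lower). PRP3 (AT3G62680) passed as lower, but its day 0 values were 1.21, 2.55 and 11.6 TPM. The PRP3 call was lost after median-of-ratios scaling and without day 0 replicate 3 (log2 difference -0.62, limma adjusted p = 0.275). It was also lost with quantile normalization, with the replicate number as a block and without day 7 replicate 3. The same held without the 50 most abundant genes and with nuclear protein-coding genes only. Of 8 tested uptake transporters 5 fell, 1 rose and 2 did not pass, with the phosphate transporter PHT1;1 (AT5G43350) going 67.3-fold down from 82.4 ± 41.1 TPM and the nitrate transporter NRT2.1 (AT1G08090) from 7.76 ± 2.41 to 0.197 ± 0.212 TPM. Adjusted over the lists alone the counts were the same except for 6 falls among the transporters. Camera adjusted p was 4.22e-06, 0.0261 and 9.41e-03 for the 3 lists, and adjusted p = 0.631, 0.631 and 0.811 with an estimated correlation. The call of the root hair list was lost with quantile normalization (adjusted p = 0.142), with the replicate number as a block (0.0501), without day 0 replicate 3 (0.0652) and without day 7 replicate 1 (0.0516), and after median-of-ratios scaling it had 3 tested members, too few for the test.

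Vascular genes went both ways. PXY (AT5G61480), the receptor that maintains cambium, rose from 20.3 ± 5.41 to 84.3 ± 24.7 TPM (4.14-fold), while its peptide ligand genes CLE41 (AT3G24770) and CLE44 (AT4G13195) fell from 39.7 ± 10.6 to 5.34 ± 3.40 TPM (7.43-fold) and from 70.8 ± 23.1 to 16.0 ± 8.38 TPM (4.44-fold; SD, n = 3 each). Of 13 tested phloem and cambium genes 4 rose, 4 fell and 5 did not pass, with limma camera adjusted p = 0.995. The xylem proteases XCP1 (AT4G35350) and XCP2 (AT1G20850) stood at 49.5 ± 4.15 and 32.3 ± 2.64 TPM at day 0 and at 38.8 ± 10.5 and 24.9 ± 10.5 at day 7, and neither passed, though both passed as lower after median-of-ratios scaling (limma adjusted p = 0.0397 and 0.0209), and XCP1 turned to a log2 difference of 0.0177 with nuclear protein-coding genes only. Of 12 tested xylem and secondary wall genes VND7 rose and 11 did not pass, with limma camera adjusted p = 0.874; after median-of-ratios scaling 1 rose and 5 fell.

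All 11 hypoxia response genes rose in callus, also after median-of-ratios scaling and when adjusted over the list alone. SUS4 (AT3G43190), a sucrose synthase, rose from 1.29 ± 0.618 to 137 ± 54.6 TPM (107-fold), and PDC1 (AT4G33070), the pyruvate decarboxylase of ethanol fermentation, from 5.56 ± 1.80 to 209 ± 61.3 TPM (37.6-fold; SD, n = 3 each), with log2 differences of 5.88 ± 0.44 and 4.99 ± 0.44 (SE, limma adjusted p = 1.19e-37 and 3.32e-28). The alcohol dehydrogenase gene ADH1 went from a mean of 45.3 to 675 TPM. Camera gave adjusted p = 8.03e-16 for the list, and adjusted p = 0.586 with an estimated correlation.

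Jasmonate and rapid stress genes mostly fell or did not pass. Of 11 tested jasmonate genes 5 fell and 6 did not pass, with the repressor gene JAZ6 (AT1G72450) 23.9-fold lower at day 7. JAZ8 (AT1G30135) had a log2 difference of -2.34 ± 0.33 (SE) and was listed at 0 in 2 of the 3 day 7 libraries. Camera adjusted p was 0.0338, and adjusted p = 0.925 with an estimated correlation; the call was also lost after median-of-ratios scaling, where 5 fell and 2 rose. Of 13 tested touch and stress genes 6 fell, 3 rose and 4 did not pass (7 fell adjusted over the list alone, and 8 after scaling; limma camera adjusted p = 0.622), with TCH4 (AT5G57560) 6.16-fold lower and WRKY46 (AT2G46400) 17.4-fold higher at day 7.

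Few secondary metabolism, chromatin and reference genes passed the test on the deposited scale. Of 12 tested glucosinolate genes 2 rose, CYP79B3 (AT2G22330, 3.98-fold) and MYB34 (AT5G60890, 3.31-fold; lost without day 7 replicate 3), 1 fell and 9 did not pass, and scaling gave 3 rises and 3 falls. Of 5 tested flavonoid genes MYB12 (AT2G47460) rose 3.54-fold and 4 did not pass, with CHS (AT5G13930) at 14.9 ± 8.26 and 11.6 ± 9.88 TPM (SD, n = 3 each). Of 17 chromatin modifiers 3 rose and 14 did not pass; the DNA demethylase ROS1 (AT2G36490) went from 1.07 ± 0.186 to 8.52 ± 2.25 TPM (7.94-fold) and the methyltransferase DRM2 (AT5G14620) rose 2.77-fold (lost when either of 2 libraries was left out), and after median-of-ratios scaling 11 rose and 2 fell. Of 11 reference genes ACT2 (AT3G18780) fell 2.96-fold (lost without day 0 replicate 2), GAPC2 (AT1G13440) rose 2.18-fold (lost with no filter and when any of 4 libraries was left out) and 9 did not pass (1 fell and 0 rose adjusted over the list alone), while scaling gave 8 falls and 2 rises. For these 4 lists limma camera gave adjusted p = 0.549, 0.995, 0.0609 and 0.571. The chromatin list was shifted up after median-of-ratios scaling (limma camera adjusted p = 3.92e-03, and adjusted p = 0.290 with an estimated correlation). Of the 28 lists with enough tested members 13 were shifted by camera with its preset correlation, 3 up and 10 down (15 at an unadjusted p below 0.05), and 0 with an estimated correlation, where the smallest adjusted p was 0.586. After median-of-ratios scaling 14 lists were shifted (0 with an estimated correlation), and 16 when rescaled without the 50 most abundant genes.

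**Figure D4:**
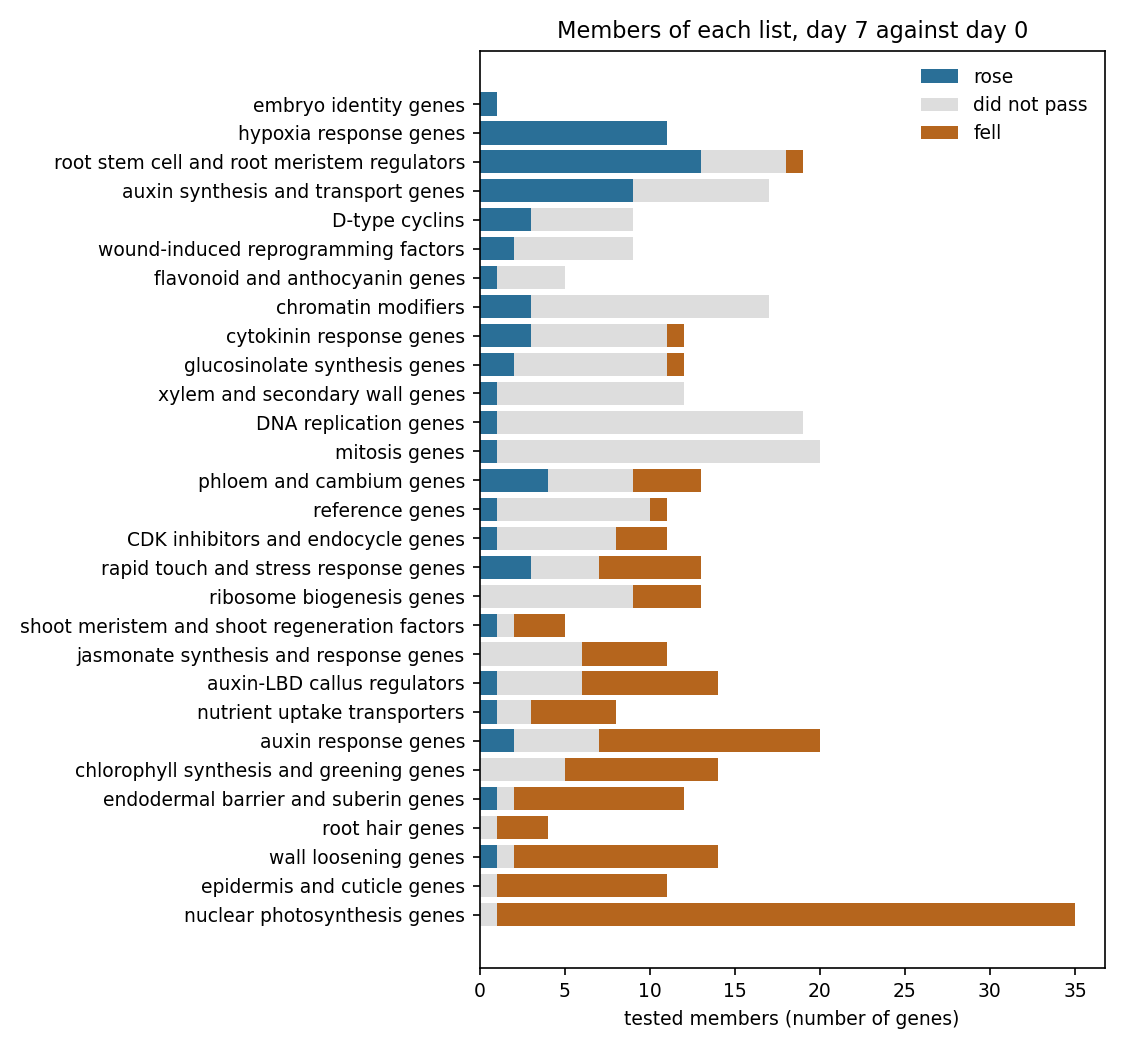
Horizontal bars give, for each of the 29 lists with a tested member, how many tested genes rose, did not pass or fell at day 7 against day 0. All 11 hypoxia genes rose and 34 of 35 photosynthesis genes fell.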

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

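The number of genes changed, 5512, depended on the scale: it was 12153 with median-of-ratios scaling, 11755 with quantile normalization, 13350 when rescaled without the 50 most abundant genes and 13428 with nuclear protein-coding genes only. Limma treat against a 1.5-fold change gave 2900. With the replicate block it was 10119, and 12074 with median-of-ratios scaling as well. Deviations of same-number libraries correlated at 0.0970, 0.156 and 0.0316, but day 0 replicates 1 and 3 correlated best with another number (0.124 and 0.0417), so pairing by number stayed open. Leaving out single libraries gave 3560 (without day 7 replicate 3) to 7219 (without day 7 replicate 2), and leaving out replicate 2 of both groups 7568. The share that rose was 31.2% to 58.9% with single libraries left out, 68.1% without the 50 most abundant genes and 69.6% with nuclear protein-coding genes only. The number changed at least 2-fold, 5276, was 3045 with pseudocount 5 and 3549 to 6002 with libraries left out.

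The number of gene lists shifted, 13, was 12 to 13 with libraries left out. It was 0 when camera estimated the correlation, on the deposited scale or with median-of-ratios scaling. The difference in plastid and mitochondrial share, -0.933, ranged from -1.36 to -0.54. Of 82 tested named genes, 73 passed. In alternatives that tested these, limma treat aside, none turned and 62 kept their call.

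Among genes that did not pass, 6 turned, and the cause was not tested. TSO2 was -0.0144 with median-of-ratios scaling, with or without the replicate block, -0.0216 without day 0 replicate 1, -0.29 without day 7 replicate 2 or replicate 2 of both groups, and up to 0.35 without day 7 replicate 1. PCNA2 was 0.11 with quantile normalization, 0.22 without the 50 most abundant genes, 0.27 with nuclear protein-coding genes only, and -0.51 to 0.18 with single day 7 libraries left out. CHS ranged from -1.41 without day 7 replicate 3 to 0.30 without day 7 replicate 2, and was 0.40 without replicate 2 of both groups. WOX5 was 0.10 without the 50 most abundant genes, 0.15 with nuclear protein-coding genes only, and -0.61 to 0.00473 with single day 7 libraries left out. WIND1 was 0.0885 with quantile normalization and 0.0459 with nuclear protein-coding genes only, where XCP1 was 0.0177.

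For 6 lists that were not shifted the direction given by camera or fry turned in some tests. The values are mean log2 differences of members minus other genes, which did not always change sign. Cytokinin response, 0.375 as reported, was 0.30 with median-of-ratios scaling, with or without the block, 0.43 without the 50 most abundant genes and 0.43 with nuclear protein-coding genes only. Xylem, 0.0508 as reported, was -0.0862 at a minimum TPM of 5, 0.0469 with median-of-ratios scaling, with or without the replicate block, 0.0508 with the block alone and in fry, and 0.0115 with quantile normalization. Phloem and cambium, 0.00422 as reported, was -0.0139 at a minimum TPM of 5, 0.00256 without the 50 most abundant genes, 0.0129 with nuclear protein-coding genes only, -0.0764 without replicate 2 of both groups, 0.00422 in fry and -0.0725 to 0.0626 with single libraries left out. Flavonoid, -0.0153 as reported, was 0.0250 with median-of-ratios scaling, 0.25 without replicate 2 of both groups and -0.34 to 0.56 with single libraries left out. Glucosinolate, 0.344 as reported, was 0.0777 with no filter on low values, and shoot meristem, -0.139 as reported, 0.0977 at a minimum TPM of 5.

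Apart from the estimated correlation and fry, 10 of the 13 lists stayed shifted throughout. Chlorophyll synthesis, root hair and jasmonate lists did not, and the root hair list had too few tested members with median-of-ratios scaling or a minimum TPM of 5. Mitosis, chromatin and ribosome biogenesis lists passed with median-of-ratios scaling, with the replicate block, without the 50 most abundant genes and with nuclear protein-coding genes only, but not with an estimated correlation (adjusted p = 0.394, 0.290 and 0.394 when scaled). Mitosis and chromatin also passed with no filter and quantile normalization, and chromatin with pseudocount 5. The number of lists was otherwise 10 to 16, and 9 in fry. Nuclear protein-coding genes only, median-of-ratios scaling with the replicate block or with an estimated correlation, and leaving out replicate 2 of both groups were added after the data had been seen.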

Other observations

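Beyond the fixed lists, 14 gene families picked after seeing the data were counted. Small auxin-up RNA genes, rapidly induced by auxin, fell in 44 of 57 tested cases and rose in 6; AT4G34770 and AT2G18010 were at 285 ± 105 and 116 ± 54.7 TPM at day 0 (SD, n = 3) and listed at 0 in all day 7 libraries, while AT4G31320 rose from 0.513 ± 0.231 to 37.3 ± 19.9 TPM. Lipid-transfer and hybrid proline-rich protein genes fell in 33 of 41 cases, class III peroxidase genes in 29 of 42, and arabinogalactan and fasciclin-like protein genes in 24 of 39. The peroxidase gene AT2G18980 fell from 361 ± 85.5 to 2.95 ± 2.79 TPM and FLA9 from 464 ± 220 to 1.69 ± 1.87 TPM. Adjusted p with an estimated correlation was 0.202, 0.202, 0.603 and 0.603 for these 4 families (limma camera).

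Aquaporin genes fell in 11 of 20 cases, with PIP2;8 rising from 6.77 ± 0.598 to 46.6 ± 19.9 TPM (SD, n = 3) against the trend. Among 32 root growth factor, CLE and RALF peptide genes 18 fell and 5 rose: RGF6 was at 142 ± 109 TPM at day 0 and listed at 0 at day 7, opposite to RGF2 and RGF3. Disease resistance genes of the NB-LRR class rose in 26 of 79 cases (14 to 37 with single libraries left out, 44 after median-of-ratios scaling and 56 when rescaled without the 50 most abundant genes) and fell in 7. The defence regulators WRKY70 and WRKY51 rose from 0.717 ± 0.631 to 55.5 ± 27.9 TPM and from 0.347 ± 0.202 to 37.5 ± 17.3 TPM, while 17 of 52 WRKY genes fell and 14 rose. Their balance depended on the scale: 25 fell and 20 rose after median-of-ratios scaling, and 20 fell and 22 rose when rescaled without the 50 most abundant genes. Ribosomal protein genes fell in 65 of 240 cases and rose in 4, after median-of-ratios scaling 200 fell, and with single libraries left out 13 to 178 fell.

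All tests of the 3 patterns below were chosen after the results had been seen. Auxin-induced callus genes such as LBD29 and GATA23 were higher at day 0 than at day 7. Exchanged group labels are argued against by epidermis and cuticle genes, which mark the organ surface and were lower under the day 7 label, with a median log2 difference of -2.47. Root material carried over with the hypocotyls was not tested and stays open: RHD6, CYP86A1, PHT1;1, WOX7 and RGF6 were higher at day 0, and PLT1, RGF2 and RGF3 lower. As a hypothesis, the day 0 tissue may already have responded to auxin when collected. Mitosis genes stood at a median of 59.3% of their day 7 level (34.9% to 108%, 20 genes). Mitosis genes do not measure an auxin response, and their small difference was already known, so the value cannot decide the hypothesis. Primary auxin response genes go with the hypothesis: 13 of 20 fell at day 7 and 2 rose. Small auxin-up RNA genes fell in 44 of 57 cases and rose in 6. Both belong to the pattern that raised the hypothesis, so they cannot decide it either.

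Summed plastid TPM, mostly plastid rRNA, was lower at day 7. Different amounts of rRNA left in the libraries are argued against only if plastid and nuclear rRNA were left in equal proportion. Summed plastid TPM per 100 TPM of nuclear rRNA was 17.9-fold lower at day 7 (means 14.4 and 0.807, n = 3), without overlap. Both shares were known when this ratio was chosen, and the mean nuclear rRNA share was higher at day 7 (24.2% against 11.4%). Removal of plastid rRNA to another degree than nuclear rRNA was not tested and stays open.

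Photosynthesis genes were high in day 0 replicate 3. The scale of that library is argued against, because after median-of-ratios scaling their ratio to replicates 1 and 2 had a median of 2.94 (quartiles 2.37 to 4.07, 35 genes). As a hypothesis, its explants may have been greener. Chlorophyll synthesis genes had a ratio of 1.68 (quartiles 1.42 to 2.02, 14 genes), which goes with that hypothesis, although plastid genes had only 1.18. The photosynthesis list was also fixed as a marker of carried-over green cotyledon, which was not tested and stays open.

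The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes changed the real split gave 5512 and the highest other 2, with 1 of 10 splits as large; for genes changed at least 2-fold the real split gave 5276 and the highest other 2, with 1 of 10. For gene lists shifted the real split gave 13 and the highest other 15, with 6 of 10 splits as large. After median-of-ratios scaling the real split gave 14 lists and the highest other 12, but 0 with an estimated correlation. Every other split mixed both days in each of its groups, so the day difference widened the spread and held gene counts low. Those splits also kept part of the day difference between their groups. The splits therefore cannot decide whether the gene or list counts arose by chance.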
